A study of Homo sapiens with 2 samples.

How the data were processed

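RNA was measured in 2 libraries of HGC27, an established human gastric cancer cell line. The cells of 1 library were transfected with an empty control plasmid and those of the other with a plasmid carrying LINC01133, a long non-coding RNA, and both were harvested 48 h later, per the labels' protocols. Messenger RNA was selected by its poly(A) tail before library preparation, per the labels' protocols, with a kit whose strand setting in counting was not given in the sources used here. Each group held 1 library, so no difference has a replicate check.

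The authors deposited 1 value per gene and library. The unit is not named by the labels; the values were read here as FPKM, fragments scaled to exon length and to the counted fragments of the library, because the deposited values have that structure. Multiplied by the merged exon length of the gene in GENCODE release 29, they fall on whole multiples of 1 step per library, within a tolerance of 0.02 of a fragment, for 94.5% of the genes with a length in the control and 94.4% in the overexpression library. Per the submitters' processing notes, Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0 and the genome build GRCh38 were used; the role of each tool and the annotation release were not given in the sources used here. How HTSeq treated fragments shared by overlapping genes was not given either, so values of overlapping genes, near-identical copies and antisense partners are uncertain.

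The step of each library gave its depth, 15666629 counted fragments in the control and 16302581 in the overexpression library, and the fragments behind each gene. Intervals are 95% and exact: Poisson for a level, and the Clopper-Pearson interval of the conditional binomial share for a ratio. They cover counting error only, since amplified fragments without molecular identifiers are not independent molecules. Genes whose value was not a whole number of fragments in both libraries carry no interval.

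The design fixed before the data were examined held a branch for counts and a branch for FPKM, and the FPKM branch was used. The log2 ratio is that of FPKM + 1, overexpression over control, which understates the difference of genes with low values. Genes with a mean FPKM of at least 1 over the 2 libraries were kept, 11945 of the 28303 genes listed, and a gene was counted as higher or lower at an absolute log2 ratio of 1 or more. No count model, p-value for the difference of a gene or SD was computed. Fisher exact tests over genes were used only for shared exons, at 50% on either strand and at 10% on the same strand. The authors' scaling to the total of counted fragments was kept. A symbol was matched to 22937 of the 28303 gene identifiers and an exon length to 28109, and gene coordinates are those of GENCODE 29 on GRCh38, counted from 1.

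The 29 gene lists were fixed before the data were examined. The median log2 ratio of the members past the filter was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. A list was called above or below matched genes when its median lay beyond the 97.5th or under the 2.5th percentile, and lists with fewer than 5 measured members have values only. Named genes were LINC01133, then among genes with a mean FPKM of at least 2 the 8 with the largest and the 8 with the smallest log2 ratio, the 4 with the largest gain and the 4 with the largest loss in FPKM, up to 4 members of each list with the largest absolute log2 ratio, and any member of the Hippo, YAP/TAZ-TEAD and earlier-work lists. Protein-coding genes at the extremes of the log2 ratio, or far from the trends described next, were named after their values were seen. Some genes that meet these rules are not reported here.

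GC content and length were taken from the longest coding transcript with a 3′ UTR, or the longest transcript of a gene that has none. A first calculation had used the longest transcript of any type by mistake, and its values had been seen when this was corrected; they are kept as an alternative. A value was found for 99.7% of the genes past the filter. Trends were fitted by lowess with a span of 0.3 and subtracted, keeping the median over all genes. The 3′ UTRs were searched for sites complementary to positions of a miRNA seed 7 bases long. For the ranking of these sites, a trend on 3′ UTR length was subtracted as well, after those on GC content and length.

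Alternatives set before the data were examined were other scalings (median of ratios, trimmed mean of M values, upper quartile), other filters and pseudocounts, a prior of 10 fragments, other fold thresholds, the mean in place of the median, unmatched random lists and, for the counts of genes and the gene lists, the subtraction of the GC content and length trends. Scaling to total counts is already part of FPKM and gave no separate value. Alternatives chosen after the data were seen were random lists matched also on GC content, protein-coding genes only, the log2 ratios of single genes with both trends subtracted, each trend subtracted alone, and the trends by the longest transcript of any type. The lists matched also on GC content used 10 bins of GC content and only 4 bins of mean expression, in place of 20.

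The calculation was tested on simulated data made from the real genes' levels and depths with counting error only, for the comparison of overexpression with control over 11961 genes. Genes simulated at 2-fold in FPKM fall under the threshold, which is set on FPKM + 1, and 11.2% of them were called in the right direction. Most true differences of 2-fold were therefore missed. Of the genes simulated at 4-fold 96.6% were called in the right direction, and of the unchanged genes 0.467% were called. The counting interval held the true ratio for 95.4% of genes. Of 100 unchanged lists of 20 genes, 2 fell outside the percentile limits, and a list raised 1.5-fold reached percentile 100. With a simulated GC trend, over 12066 genes, 324 unchanged genes passed the threshold before its subtraction and 70 after it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.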

Results

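Gene expression was profiled by poly(A)-selected RNA sequencing in HGC27 gastric cancer cells carrying a control plasmid or a plasmid expressing LINC01133, with 1 library per group. The depth was 15666629 counted fragments in the control library and 16302581 in the overexpression library. FPKM was above 0 for 21677 of the 28303 genes listed in the control and for 23588 in the overexpression library. Because each group held a single library, the differences below have no replicate check and describe these libraries.

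LINC01133 itself was far higher in the library labelled as overexpressing it. Its FPKM was 0.0809 in the control (95% counting interval 0.0220 to 0.207) and 1.44 in the overexpression library (1.13 to 1.81), from 4 and 74 fragments. The ratio was 17.8 (6.66 to 67.0), and the log2 ratio of FPKM + 1 was 1.17. The gene (ENSG00000224259) is a long intergenic non-coding RNA on the plus strand of chromosome 1, from 159961218 to 159984750 on GRCh38, with 3155 bases of merged exons. Its level in the overexpression library was low beside that of most genes named here, and its mean lay under the filter used for the counts that follow.

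The question the design addresses is which genes differ when LINC01133 is overexpressed. Many more genes were higher than lower: of 11945 genes past the filter, 1421 (11.9%) were at least 2-fold higher in the overexpression library and 53 (0.444%) at least 2-fold lower. Here and below, 2-fold in counts of genes refers to FPKM + 1. Among the 10335 protein-coding genes the numbers were 1207 and 5. The median log2 ratio was 0.10, with quartiles of -0.28 and 0.63. After scaling by the trimmed mean of M values, which shifted all log2 ratios of FPKM by 0.21, 897 genes were higher and 107 lower.

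The difference between the libraries followed the base composition of the transcripts. AT-rich transcripts were higher in the overexpression library and GC-rich transcripts slightly lower. In the tenth of genes with the lowest GC content, from 26.9% to 38.7%, the median log2 ratio was 1.14 and 60.7% of the genes were at least 2-fold higher. In the tenth with the highest GC content, from 62.3% to 83.6%, the median was -0.39 and 1.18% were at least 2-fold higher. Across genes, which are not independent replicates, the Spearman correlation of the log2 ratio with GC content was -0.801 over 11913 genes and -0.854 over the protein-coding genes. It was -0.418 for lincRNA genes and -0.446 for antisense genes. With the GC content and length trends subtracted, 196 genes were at least 2-fold higher and 94 lower. The log2 ratio also differed by expression level. Its median was 0.28 at a mean FPKM of 1 to 2, 0.30 at 2 to 5, 0.01 at 5 to 20, -0.27 at 20 to 100 and -0.37 at 100 or more. This difference was not separated from that by GC content.

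**Figure D1:**
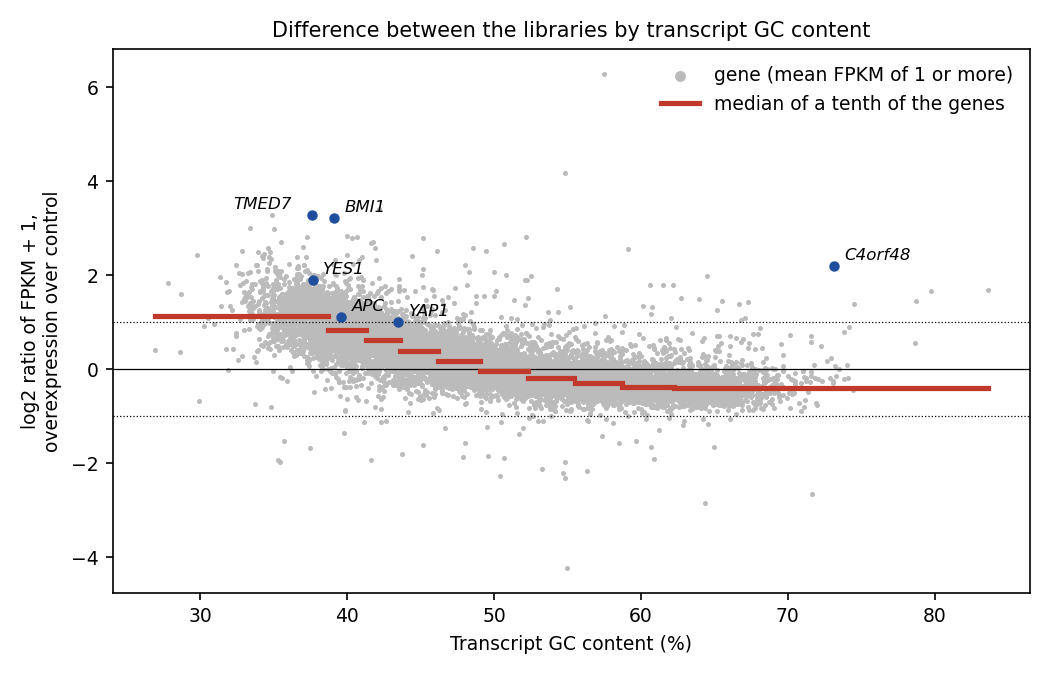
Log2 ratio of FPKM + 1 (overexpression over control) against transcript GC content in percent, 1 point per gene with a mean FPKM of 1 or more; red bars are medians of 10 GC classes of equal size and dotted lines mark 2-fold. The median was 1.14 in the tenth with the lowest GC content and -0.39 in the tenth with the highest.

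Of 8 measured genes that earlier work had linked to LINC01133, 3 were at least 2-fold higher in the overexpression library. YES1, a Src-family tyrosine kinase, had an FPKM of 6.48 in the control and 27.0 in the overexpression library, a ratio of 4.16 (3.78 to 4.58). YAP1, the transcriptional coactivator restrained by the Hippo pathway, had 7.94 and 17.0, a ratio of 2.14 (1.96 to 2.33). APC, a component of the beta-catenin destruction complex, had 1.24 and 3.82, a ratio of 3.09 (2.67 to 3.58). By median-of-ratios scaling and by the trimmed mean of M values, YAP1 and APC fell under 2-fold in FPKM + 1, while YES1 stayed above it. All 3 transcripts were AT-rich, with GC contents of 37.7%, 43.5% and 39.6%, and their log2 ratios of 1.90, 1.01 and 1.11 were 0.89, 0.52 and 0.24 with the trends subtracted. SRSF6 (log2 ratio 0.46), a splicing factor, and EZH2 (0.54), a histone methyltransferase, lay between, and KDM1A (0.05), KLF2 (-0.11) and the cell cycle inhibitor CDKN1A (-0.43) did not reach 2-fold. With the trends subtracted SRSF6 turned to -0.37, KLF2 to 0.42 and CDKN1A to 0.01, while EZH2 was at 0.25 and KDM1A at 0.17. CDH1, encoding E-cadherin, had 2 fragments in the control and 1 in the overexpression library. The list's median of 0.50 over 8 measured members was at percentile 97.3 of expression-matched lists, and 0.24 at percentile 96.9 with the trends subtracted, within the limits both times. Against lists matched also on GC content the median of 0.50 was at percentile 70.4, and against unmatched lists at 89.6.

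**Figure D2:**
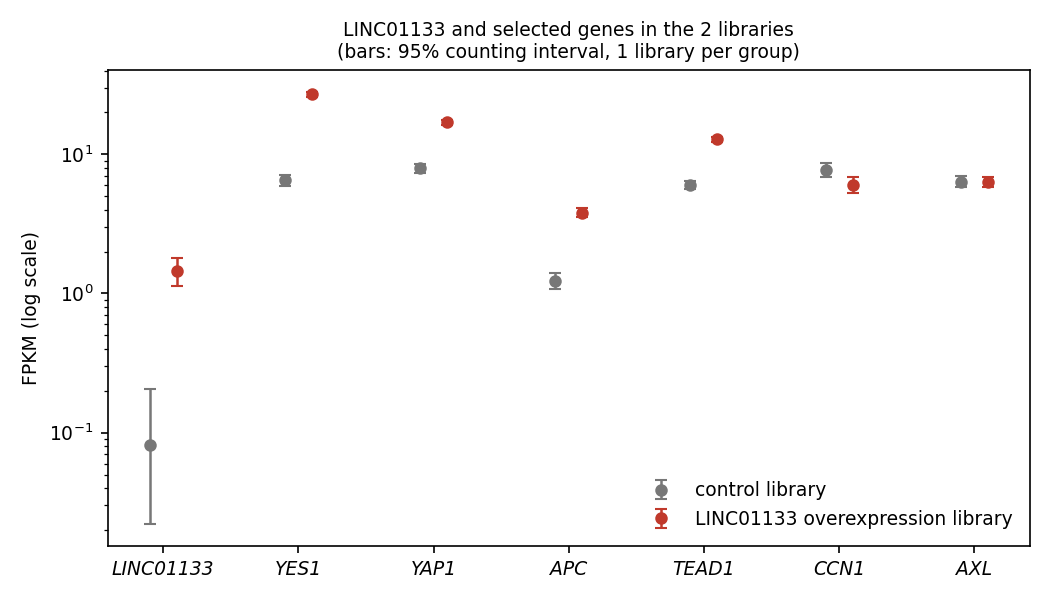
FPKM on a log scale of LINC01133 and 6 further genes in the control library (grey) and the LINC01133 overexpression library (red), 1 library per group; bars are 95% counting intervals. LINC01133 was at 0.0809 and 1.44, and YES1 at 6.48 and 27.0, while AXL was at 6.35 and 6.31.

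Of 25 measured genes on the list of Hippo pathway components, 5 were at least 2-fold higher and 0 lower, and 18 had a log2 ratio above 0. The list holds the kinase cascade that restrains YAP1, but also YAP1 itself, its TEAD partners and the kinases YES1 and SRC. YES1 and YAP1 are also among the genes of earlier work above. Beside YES1 and YAP1, the 5 were the kinase adaptor MOB1B (FPKM 0.783 and 4.93), its paralogue MOB1A (12.7 and 35.5) and the kinase TAOK1 (2.34 and 8.92). With the trends subtracted none of the 5 reached 2-fold, and the log2 ratios of MOB1B, MOB1A and TAOK1 went from 1.73, 1.41 and 1.57 to 0.41, 0.36 and 0.68. The YAP1 partner TEAD1 had 6.00 and 12.8 (log2 ratio 0.98, then 0.28), while TEAD3 (13.7 and 9.10) and TEAD4 (28.9 and 19.95), with GC-rich transcripts, were lower, and their log2 ratios of -0.54 and -0.51 were -0.10 and 0.00 with the trends subtracted. The list's median of 0.54 was at percentile 98.2, above matched genes. With the trends subtracted it was 0.16 at percentile 83.3, and against lists matched also on GC content 0.54 was at 91.0, no longer above. Among 17 measured target genes of YAP/TAZ and TEAD, 0 were at least 2-fold higher or lower, and the median was 0.04, at percentile 24.7 (0.05 at 22.6 with the trends subtracted). The direction of that median turned with the scaling, to -0.16 by the trimmed mean of M values. CCN1 had an FPKM of 7.70 and 6.02, CCN2 0.955 and 0.734, IGFBP3 49.2 and 44.0, and TGFB2 1.35 and 2.64, a log2 ratio of 0.63 that turned to -0.28 with the trends subtracted.

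Reported targets of miR-145-5p had a median log2 ratio of 0.39 over 18 measured genes, at percentile 93.8, and 0.24 at percentile 98.3 with the trends subtracted. Against lists matched also on GC content it was at 85.2, within the limits. Beside YES1, the kinase ROCK1 (ratio 3.70, 3.31 to 4.13), the membrane skeleton protein ADD3 (3.14, 2.76 to 3.58) and NRAS (2.80, 2.54 to 3.08) were at least 2-fold higher, and MYC had FPKM values of 190 and 153. The log2 ratios of ROCK1, ADD3 and NRAS went from 1.53, 1.38 and 1.38 to 0.74, 0.55 and 0.43 with the trends subtracted, under 2-fold. That of MYC went from -0.31 to -0.01. Target genes of Wnt and beta-catenin had a median of 0.03 over 15 genes, at percentile 53.2 (0.19 at 92.5 with the trends subtracted), and 0 were at least 2-fold apart. That median turned to -0.14 by the trimmed mean of M values.

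Genes of the G2/M phase of the cell cycle were above matched genes with and without the trends. Of 24 measured genes 6 were at least 2-fold higher and 0 lower, and 19 had a log2 ratio above 0. The median of 0.59 lay at percentile 99.99, and at 99.99 again with the trends subtracted (median 0.24). The mitotic kinesin KIF11 had an FPKM of 11.2 and 40.5 (ratio 3.62, 3.35 to 3.91), the kinesin-like CENPE 0.994 and 7.03, the mitotic kinase CDK1 14.97 and 45.9, and topoisomerase TOP2A 40.5 and 119. Their log2 ratios of 1.77, 2.01, 1.56 and 1.53 were 0.81, 0.76, 0.58 and 0.62 with the trends subtracted, each under 2-fold. Genes of the G1/S phase had a median of 0.07 over 22 genes, at percentile 96.9 (0.11 at 98.5 with the trends subtracted, and 94.6 against lists matched also on GC content). The median turned to -0.12 by the trimmed mean of M values. The licensing factor CDT1 was lower, with an FPKM of 53.7 and 33.2 and a log2 ratio of -0.68, or -0.20 with the trends subtracted.

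Hypoxia response genes were below matched genes, with a median of -0.31 over 20 genes at percentile 0.63, and of -0.08 at percentile 1.13 with the trends subtracted. By FPKM + 1 none was at least 2-fold higher or lower. Carbonic anhydrase CA9 had an FPKM of 4.55 and 1.91 and the secreted ANGPTL4 30.2 and 16.1, while the collagen hydroxylase subunit P4HA1 had 18.1 and 36.7. The log2 ratios of CA9 and ANGPTL4 went from -0.93 and -0.87 to -0.42 and -0.33 with the trends subtracted. With genes of a mean FPKM of at least 5 only, the percentile was 27.2. Immediate early genes (median -0.32 over 15 genes, percentile 0.83), BCL2 family genes (-0.27 over 14, percentile 0.92) and type I interferon response genes (-0.25 over 12, percentile 2.27) were also below. With the trends subtracted they were within the limits, at -0.02 (12.1), 0.01 (18.1) and 0.09 (48.3), so the last 2 medians turned. As deposited, the mean log2 ratio of the interferon list was 0.01, against its median of -0.25. FOS, an immediate early transcription factor, had 2.70 and 0.852, and JUN 6.85 and 3.40. The survival factor MCL1 had 25.1 and 43.6, and the interferon-induced IFI6 9.59 and 5.74.

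Several lists lay within the limits as deposited and outside them with the trends subtracted. Nuclear-encoded oxidative phosphorylation genes had a median of -0.25 over 34 genes at percentile 44.0, and then -0.19 at 0. Their member SDHD was higher, with FPKM values of 2.04 and 14.9 (log2 ratio 2.39, then 1.81). Cytosolic ribosomal protein genes had -0.25 over 71 genes at percentile 90.04, and then -0.21 at 0, while RPS23 was higher in the overexpression library, with FPKM values of 12.4 and 23.1. NRF2 target genes had -0.41 over 14 genes at 3.27, and then -0.21 at 0.16. ATF4 and unfolded protein response genes had -0.22 over 28 genes at 33.5, and then -0.12 at 0.83, but against lists matched also on GC content they were at 46.1, within the limits. Heat shock genes had a median of 0.04 over 13 genes at percentile 84.6, and then 0.20 at 98.8, but against lists matched also on GC content they were at 64.9, within the limits. The chaperone HSP90AA1 had 190 and 442 (log2 ratio 1.22, then 0.94). The heat shock median turned to -0.03 by the trimmed mean of M values.

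**Figure D3:**
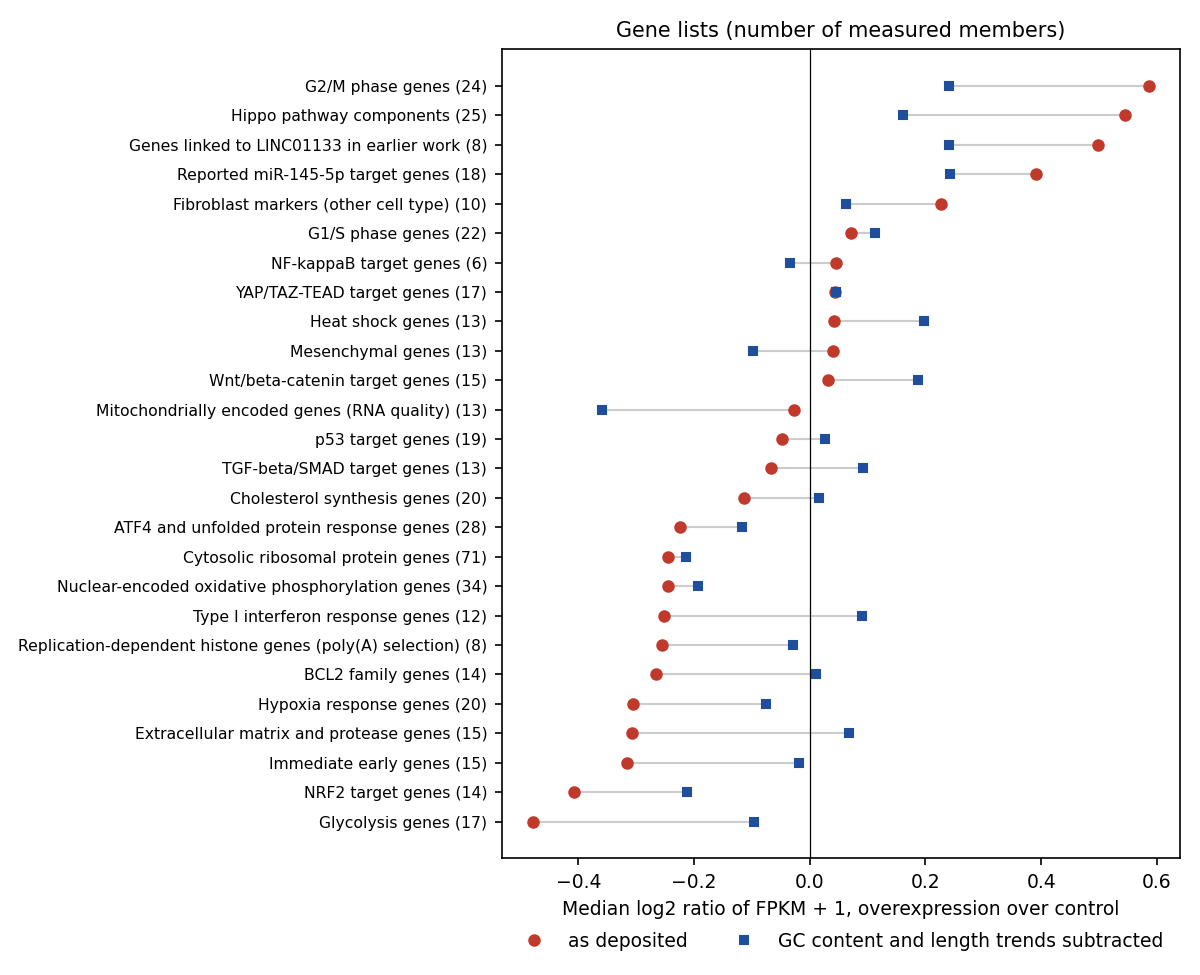
Median log2 ratio of FPKM + 1 (overexpression over control) of the 26 gene lists with at least 5 measured members, as deposited (red circles) and with the GC content and length trends subtracted (blue squares); numbers in brackets are measured members. G2/M phase genes were at 0.59 and 0.24, and hypoxia response genes at -0.31 and -0.08.

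The following lists lay within the limits as deposited and with the trends subtracted, and the values in brackets are the percentile, then the median and percentile after subtraction. Glycolysis genes had a median of -0.48 over 17 genes (3.14, then -0.10 at 18.8), but were below matched genes at 1.61 against lists matched also on GC content, and ALDOA had FPKM values of 445 and 256. Extracellular matrix and protease genes had -0.31 over 15 genes (11.04, then 0.07 at 76.9) and cholesterol synthesis genes -0.11 over 20 (64.4, then 0.02 at 50.6), of which 4 were at least 2-fold higher, among them STARD4 (FPKM 1.08 and 6.76; log2 ratio 1.90, then 0.60) and the isomerase IDI1 (9.37 and 32.1; 1.68, then 1.01). The p53 target genes had -0.05 over 19 genes (24, then 0.03 at 21.9), and CCNG1 had 10.4 and 42.8 (log2 ratio 1.94, then 1.05) and the cytokine GDF15 3.88 and 1.29 (-1.09, then -0.52). TGF-beta and SMAD target genes had -0.07 over 13 genes (29.7, then 0.09 at 64.7), but were above matched genes at 97.7 against lists matched also on GC content. NF-kappaB target genes had 0.05 over 6 (39.8, then -0.03 at 13.5), a median that turned to -0.13 by the trimmed mean of M values. Mesenchymal genes had 0.04 over 13 genes (69.7, then -0.10 at 5.44), or -0.13 by that scaling, with the repressor ZEB1 at 3.06 and 7.82 (log2 ratio 1.12, then 0.16) and SNAI1 at 30.5 and 19.8 (-0.60, then -0.13). Of 17 epithelial genes with values, 0 had a mean FPKM of at least 1.

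Lists that speak of sample composition and RNA quality were as follows. All genes of the mitochondrial chromosome, its ribosomal RNAs included, took 10.3% of the fragments in the control and 10.2% in the overexpression library. Within this share the ribosomal RNA MT-RNR2 went from 187946 to 317828 fragments. The list of 13 mitochondrially encoded genes holds protein-coding genes only, of which 4 were higher in the overexpression library. Its median was -0.03 (94.5, then -0.36 at 0.03, below matched genes). Replication-dependent histone genes, which mostly lack a poly(A) tail, had -0.25 over 8 genes (3.16, then -0.03 at 18.9). Fibroblast markers had 0.23 over 10 genes (87.8, then 0.06 at 68.0), and POSTN had FPKM values of 33.7 and 98.8 (log2 ratio 1.52, then 0.66). The 4 measured gastric lineage markers had a median of -0.22 and the 2 measured blood and endothelial markers -0.28, too few for a percentile, and both turned with the trends subtracted, to 0.17 and 0.23.

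The largest log2 ratios past a mean FPKM of 2 belonged partly to small or repeated transcripts. The 5.8S ribosomal RNA gene RNA5-8SN2 on chromosome 21 (8212572 to 8212724) had FPKM values of 1.25 and 174, and the lincRNA ENSG00000281181 in the same ribosomal DNA region (8437629 to 8438551) had 575 and 115. The smallest log2 ratio, -4.23, was that of the lincRNA ENSG00000278996 in that region, with 18.7 and 0.0491 from 730 and 2 fragments, while a copy of equal length, ENSG00000280441, had 18.3 and 10.7. These are near-identical copies, so their values are uncertain. The protein-coding genes at the top were TMED7, a vesicle cargo receptor (0.0984 and 9.72, from 6 and 617 fragments), BMI1, a Polycomb protein (0.387 and 11.9, from 26 and 834 fragments), and GMFB (1.67 and 20.4). Another gene on the same strand shared 24.01% of the exon bases of TMED7 and 23.3% of those of BMI1. In FPKM itself, the mitochondrial ribosomal RNA MT-RNR2 gained most, from 7695 to 12505, and MT-CO1 lost most, from 20562 to 17720, while the elongation factor EEF2 went from 3880 to 2466.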

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

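Random lists matched also on GC content, protein-coding genes only, the log2 ratios of single genes with both trends subtracted, the trends subtracted singly and the trends by the longest transcript of any type were chosen after the data were seen. No paired analysis was possible because each group held 1 library. Depth limits the low genes most, such as LINC01133 with 4 fragments in the control. Where a value below moved, the cause was not tested.

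The 1421 genes at least 2-fold higher became 919 by median-of-ratios scaling, 897 by the trimmed mean of M values, 656 at a mean FPKM of at least 5, 2244 with a pseudocount of 0.1, 3199 at 1.5-fold and 92 at 4-fold. They became 196 with the GC content and length trends subtracted, 205 by the longest transcript of any type and 216 with the GC content trend alone. The 53 genes at least 2-fold lower became 103, 107, 10, 127, 632 and 8 in the order of the first sentence, 109 without a filter, 30 with a prior of 10 fragments, 25 with an interval that leaves out 1 and 5 among protein-coding genes. They became 94 with both trends subtracted, 95 by the longest transcript of any type, 84 with the GC content trend alone and 83 with the length trend alone. The log2 ratio of LINC01133 was 3.09 with a pseudocount of 0.1.

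The lists' percentiles follow. With the GC content and length trends subtracted, and in brackets by the longest transcript of any type, the calls ended for Hippo components at 83.3 (86.5), BCL2 family genes at 18.1 (18.8), interferon response genes at 48.3 (38.5) and immediate early genes at 12.1 (17.3). Calls appeared for miR-145-5p targets at 98.3 (98.6), G1/S genes at 98.5 (99.4), heat shock genes at 98.8 (99.5), ATF4 and unfolded protein response genes at 0.83 (0.18), NRF2 targets at 0.16 (0.52) and oxidative phosphorylation genes at 0 (0), and on the opposite side of the middle for ribosomal protein genes at 0 (0) and mitochondrially encoded genes at 0.03 (0.05). No list changed its call between these definitions of the transcript.

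Against random lists matched on GC content the values were 91.0 for Hippo components, 3.25 for BCL2 family genes, 6.82 for interferon response genes and 11.6 for immediate early genes, without a call. Of the calls that appeared with the trends subtracted, those of miR-145-5p targets at 85.2, G1/S genes at 94.6, heat shock genes at 64.9 and ATF4 genes at 46.1 did not appear here. They were 97.7 for TGF-beta targets, 0.155 for ribosomal protein genes and 0.425 for mitochondrially encoded genes, on the opposite side, and 1.61 for glycolysis genes, 0.09 for NRF2 targets and 0.01 for oxidative phosphorylation genes. Against unmatched random lists they were 3.68 for interferon response genes, 0.78 for ATF4 genes, 0 for glycolysis genes, 0.945 for extracellular matrix genes, 0.05 for NRF2 targets, 0 for ribosomal protein genes and 0.26 for oxidative phosphorylation genes. With 20 expression bins the ribosomal protein genes were at 90.04. The 4 expression bins of the GC-matched lists may therefore leave part of a difference in expression unmatched.

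By median-of-ratios scaling, and in brackets by the trimmed mean of M values, the values were 98.7 (98.7) for miR-145-5p targets, 3.08 (2.98) for interferon response genes and 0.19 (0.24) for histone genes. At a mean FPKM of at least 5 they were 96.6 for Hippo components, 97.52 for the earlier-work genes, 99.8 for miR-145-5p targets, 97.9 for G1/S genes, 21.3 for BCL2 family genes, 3.80 for immediate early genes, 98.3 for heat shock genes and 27.2 for hypoxia genes. Without a filter they were 97.8 for the earlier-work genes, 3.28 for interferon response genes, 3.04 for hypoxia genes, 1.41 for NRF2 targets and 0.03 for histone genes. With the mean of the list they were 97.4 for Hippo components, 98.95 for the earlier-work genes, 2.82 for BCL2 family genes, 10.1 for interferon response genes, 0.66 for glycolysis genes and 1.46 for histone genes. With a pseudocount of 0.1 the Hippo components were at 97.4. G2/M genes kept their call under every alternative run, and hypoxia genes lost theirs only in the filter alternatives given above.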

Other observations

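The tests of the authors' scaling, of at least 10% shared exon bases, and of few fragments were chosen after the result was seen, and so was the use of an interval in judging YES1, YAP1, APC and the miRNA sites, as were the families of genes grouped by symbol.

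Of 15 gene families, 3 lay outside the limits as deposited and on the same side with the GC content and length trends subtracted. Splicing factors of the SRSF and HNRNP families had a median log2 ratio of 0.54 over 32 genes, at percentile 100 of expression-matched lists, and then 0.09 at 98.7. Kinesins, some of which are also in the G2/M list, had 0.43 over 27 genes, at percentile 97.8, and then 0.23 at 99.2. Solute carriers had -0.09 over 177 genes, at percentile 0.02, and then 0.02 at 0.7. The position was lost by zinc finger genes at 98.97 and then 95.4, DEAD and DEAH helicases at 99.95 and then 89.2, translation initiation factors at 98.8 and then 84.4, and ubiquitin-specific proteases at 99.3 and then 4.62. HOX genes had 0.15 over 26 genes, at percentile 50.2, and then 0.48 at 100, with a median GC content of 54.8%. Complex I genes, some of which are also in the oxidative phosphorylation list, had -0.17 over 40 genes, at percentile 25.4, and then -0.20 at 0. The other 6 families lay within the limits both times. In the ribosomal DNA region of chromosome 21, the FPKM of 4 lincRNA genes of equal length summed to 584 in the control and 134 in the overexpression library, while that of 3 genes for 5.8S RNA summed to 38.4 and 198.

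Many more genes were at least 2-fold higher than lower in the overexpression library. The authors' scaling alone is argued against: after centring on the median, 1140 genes were higher and 71 lower, a quotient of 16.1. Release of miR-106a-3p targets beyond the trends is argued against too, but only as a higher median of the genes with its site. Its site ranked at percentile 12.7 of 630 words of the same composition with the GC content, length and 3′ UTR length trends subtracted, and at 69.2 before subtraction. The difference in median of -0.02 (bootstrap interval -0.03 to 0.002) lay below the 0.02 of the 90th percentile word. How strong a release the ranking could detect was not tested. The miR-145-5p site ranked at 53.8 of 420 (62.1 before subtraction), with a difference of 0.01 below the 0.02 of the 90th percentile word. Its bootstrap interval of -0.01 to 0.03 reaches that value, which keeps it open. Subtraction also took away most of the genes at least 2-fold higher, so the ranks after it cover only release beyond the trends. The difference of the log2 ratio by expression level was not tested as an explanation. A GC content trend between the libraries is a candidate explanation, as the number of genes at least 2-fold higher with it subtracted was 15.2% of the number before, against 73.1% for the length trend, a share that decides nothing for length. The trend was also present in 615 long non-coding genes, with a Spearman correlation of -0.437 against -0.854 in protein-coding genes. Its bootstrap interval of -0.505 to -0.366 was wholly negative, which argues against a trend confined to messenger RNAs, for these genes. Whether the trend is weaker outside messenger RNAs by the limit set for the test stays undecided, since the interval spans that limit. With 1 library per group, an effect of LINC01133 on AT-rich transcripts also stays open, untested.

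YES1, YAP1 and APC were higher in the overexpression library. Among the 200 protein-coding genes nearest in GC content, APC stood at percentile 69 (exact interval 62.1 to 75.3) and YAP1 at 93.5 (89.1 to 96.5), so the GC content trend may account for both. YES1 stood at percentile 97 (93.6 to 98.9), with 6 of the 200 genes above it, and the interval spans the limit set for the test, so this decides nothing. By the longest transcript of any type the percentiles were 71, 93 and 97. An effect of LINC01133 on these genes stays open, untested without a second library.

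Among protein-coding genes with a mean FPKM of at least 2, 14 had a log2 ratio of 1.5 or more with both trends subtracted, among them C4orf48, BMI1, PDF and TMED7. The counting interval reached below 2-fold in 0 of the 11 with whole fragments, 0%. These genes were picked for large differences in the same counts, and the others of the 14 have no interval. This therefore does not decide whether few fragments played a part. At least 10% of the exon bases were shared with another gene on the same strand in 50% of the 14, against 4.16% of 8923 other genes (one-sided Fisher exact p = 6.08e-07, over genes), so the assignment of fragments to overlapping genes may contribute to these values. Sharing of at least 50% was set first and tested in the same way. It was seen in 0% on the same strand and 0% on the opposite strand, but with an upper bound of 23.2% these decide nothing. By the longest transcript of any type 16 genes reached the limit of 1.5, 14 of them the same and 7 with shared exon bases. No biological explanation was tested.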
